A study of Mus musculus with 6 samples.

How the data were processed

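RNA was measured in immune cells sorted from the hearts of mice that express ovalbumin in the heart and that had received ovalbumin-specific CD8 T cells (OTI cells). Per the labels, the sorted cells were positive for CD45, the pan-leukocyte antigen, and negative for CD90.2 (Thy1), a T cell antigen, so the gate was meant to hold immune cells other than T cells. Per the labels' protocols, RNA from the lysed cells was made into non-directional libraries with a SMART-seq V4 ultra-low-input kit, which amplifies full-length complementary DNA, and sequenced as read pairs. The labels give 3 libraries as treated with immune checkpoint inhibitors (ICI, 200 µg of an antibody against CTLA-4 and 200 µg of an antibody against PD-1) and 3 as treated with isotype control antibody, numbered 1 to 3 as biological replicates in each group, and 1 batch date for all 6.

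The authors deposited 1 table of raw counts per Ensembl gene, with no normalization, for 57010 genes and 6 libraries. The submitters' processing notes name STAR 2.7.10a, Salmon 1.10.1 and the genome build GRCm39, without saying which step each served; the annotation release, the strand setting and any gene filter are not given in the sources used here. The deposited counts were whole numbers and entered the tests as they stand; whether they are rounded estimates is not given in the sources used here. Each column was tied to its sample by the library name in the label. Gene symbols came from a name table matched on Ensembl identifiers, which covered 52029 identifiers (91.3%). The identifiers without a symbol held at most 0.276% of a library's counts and included 348 of the tested genes. Because the annotation used here for names, transcript length and GC content belongs to an older mouse build than GRCm39, no coordinates are given. The libraries carry no strand, so reads of overlapping and antisense genes cannot be told apart, and members of families with near-identical copies (haemoglobin, Bcl2a1, Hspa1a and Hspa1b, class I histocompatibility and guanylate-binding protein genes) are uncertain one by one.

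The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with limma 3.58.1, with TMM normalization factors, robust dispersions and the default filter on low counts (filterByExpr, minimum count 10), which kept 14575 genes with 99.9% of the counts. All adjusted p-values for genes are from this test with Benjamini-Hochberg adjustment over the 14575 genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and the F statistic. CPM values in the text are counts scaled to a common total, on library totals, as mean ± SD of 3 libraries, so a fitted fold can differ from the ratio of 2 printed CPM means by the normalization factors. The 34 gene lists (responses, pathways, cell states and cell type markers; 682 members, of which 681 were found in the annotation) were tested with camera, a competitive test of the list against all other tested genes, at an inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over 34 lists. Each list was also tested with the correlation estimated from the data and with fry. Cell type lists describe RNA in a bulk library, not cells. Single values per library were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries. Intervals on ratios of low counts are exact 95% binomial intervals, and a group at 0 was set to 3 counts over the group, with the smaller of the bounds from pooled counts and from mean CPM given; both cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

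The groups, the test, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 called genes with the largest rise and the 10 with the largest fall among genes with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out predicted genes and receptor segments; up to 4 members of each list with the smallest p; and always Ptprc, Thy1, Tnf, Tnfrsf1a, Tnfrsf1b, Ifng, Cd274, Pdcd1 and Ctla4. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here. The other settings fixed in advance were DESeq2 1.42.0 and limma-voom; RLE and upper-quartile factors and library totals alone; no filter and a strict filter (50 counts in 3 libraries); the legacy quasi-likelihood fit and a fit without robust estimation; a replicate block; each replicate left out in turn; a test against a 1.5-fold change (glmTreat); and the genes of other cell types left out. Thinning to the lowest total, removal of a transcript length or GC trend (lowess span 0.3), a sex term and the male libraries alone were added after the data were seen.

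The total counts ran from 21528274 to 30736316 per library. Replicates of a group were compared by a chi-square of their counts, which was between 13.8 and 37.4 per degree of freedom for the 6 pairs, so no pair agreed within sampling noise. The labels call the libraries biological replicates but do not say how many animals each holds. The fit was tested on simulated data with the means, dispersions and totals of these libraries, in 10 runs each. With 200 changed genes planted for this comparison and 14206 to 14247 genes tested, it recovered 33.1% of the genes changed 1.5-fold, 70.7% of those changed 2-fold and 91.5% of those changed 4-fold, and 9.99% of its calls were false (range 5.84 to 13.7), above the nominal 5%. The legacy fit gave 9.74% false calls in the same setting. With 8000 genes planted and 14241 to 14290 tested, nearer to the number called in the data, it recovered 68.7%, 87.3% and 98.6% of the genes at these 3 fold sizes, and 2.16% of the calls were false. Of 100 simulated lists of 25 unchanged genes, camera called 0 after adjustment, and 0 had an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so this does not test camera on lists of correlated genes. In the data the estimated correlation ran from -0.0778 for plasmacytoid dendritic cell genes to 0.894 for class I presentation genes. Figures were drawn with matplotlib 3.10.9.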

Results

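The data were counts per gene for 6 libraries of CD45-positive, CD90.2-negative cells from mouse hearts, 3 labelled ICI and 3 labelled isotype. Total counts were 22794472, 23713009 and 21528274 in replicates 1, 2 and 3 labelled ICI and 29543157, 24657436 and 30736316 in those labelled isotype. The series title names myocarditis induced by checkpoint inhibitors and its dependence on TNF from CD8 T cells and on signalling through the receptor TNFR2. The design implies 1 comparison, which asks how the non-T immune cells of the heart differed between mice given antibodies against CTLA-4 and PD-1 and mice given isotype antibody. Per the labels' protocols the checkpoint antibodies induced myocarditis, and the sample titles of both groups, isotype included, name myocarditis. Groups are named below by their labels, because the direction of the differences rests on them.

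Most of the transcriptome differed between the groups. Libraries labelled ICI held abundant transcripts of heart-resident macrophages, such as Cd163, Lyve1 and Fcna, that were close to absent from libraries labelled isotype. Libraries labelled isotype held more of Nos2, Gbp11, Arg1 and Chil3. Most interferon gamma response, glycolytic, nuclear respiratory chain and cell cycle genes were also higher there. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.659, 0.0977, 0.571 and 0.659). Of 14575 genes tested, 10040 (68.9%) were called by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 5102 higher and 4938 lower in the libraries labelled ICI. Called changes of more than 4-fold were more often rises (1615 genes) than falls (406 genes). The values of the groups did not overlap for 10712 genes (73.5%), where chance gives 10%. Against a 1.5-fold change 5520 genes passed, 3110 higher and 2410 lower. The split depends on the scaling: with upper-quartile factors it was 6155 higher and 3849 lower, and with library totals alone 6255 and 3724, as these scalings moved the median log2 fold change of all genes from 0.03 to 0.21 and 0.23.

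The groups separated along the first principal component of the 500 most variable genes, which held 92.6% of the variance. Spearman correlations across genes ranged from 0.988 to 0.994 within groups and from 0.891 to 0.920 between them; genes are not independent replicates. Several library measures moved with the groups. More genes were detected in every library labelled ICI (21470 ± 113 against 20120 ± 963, SD, exact two-sided permutation p = 0.1), although their total counts were lower. Total counts, the share of mitochondrial transcripts (0.783% ± 0.078 in libraries labelled ICI and 0.446% ± 0.029 in libraries labelled isotype, SD, n = 3 each), the share of ribosomal protein transcripts (0.643% ± 0.008 and 1.17% ± 0.10), Malat1 and haemoglobin each separated the groups, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. Replicate 3 of each group carried more Xist counts (2786 for ICI and 1844 for isotype) than Y-linked counts (6 and 130), while replicates 1 and 2 of each group carried Y-linked counts of 3620 to 5821. Whether isotype replicate 3, with its 130 Y-linked counts, held RNA of females alone was not settled.

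Of the 34 gene lists, camera called 13, 7 higher and 6 lower in the libraries labelled ICI; 0 were called with an estimated correlation (3 had an unadjusted p under 0.05), and fry called 28. With a sex term, added after the data were seen, camera called 20 lists. The further ones were type I interferon (adjusted p = 0.0186) and monocyte genes (0.0186), lower, and conventional dendritic cell (0.0186), natural killer (0.0433), T cell (0.0345), mast cell (0.00515) and erythroid genes (0.0181), higher. Member counts below are over all genes tested; adjusted over the list alone they were the same unless stated. Resident macrophage genes had the highest list median. All 23 measured members of this list were higher in the libraries labelled ICI, over all genes tested and adjusted over the list alone, with a median fold of 80.6 (camera adjusted p = 4.25e-47). The call was lost at adjusted p = 0.0977 with an estimated correlation. Lyve1 (ENSMUSG00000030787), the hyaluronan receptor of perivascular resident macrophages, reached 580 ± 71.3 CPM (SD, n = 3 here and below) against 1.44 ± 0.279 CPM, a log2 fold change of 8.44 (SE 0.16, edgeR adjusted p = 1.03e-09). Fcna, which encodes ficolin A, was 163-fold higher, Pf4 68.9-fold and Ltc4s, leukotriene C4 synthase, 48.8-fold. The 10 largest rises included the haemoglobin scavenger receptor Cd163 (ENSMUSG00000008845) at 1029 ± 131 CPM against 0.884 ± 0.480 CPM, a 979-fold difference (log2 fold change 9.93, SE 0.29, edgeR adjusted p = 9.3e-08). Fcrls at 579 ± 119 CPM against 0.332 ± 0.326 CPM, Slco2b1 at 442 ± 55.9 CPM against 0.345 ± 0.0683 CPM, and the scavenger receptor Colec12 at 171 ± 28.6 CPM against 0.183 ± 0.124 CPM were among them. Without isotype replicate 3 the folds of Fcrls and Colec12 moved from 1415 and 769.9 to 2874 and 1251. The complement receptor Vsig4 was 656-fold higher and the C-type lectin Cd209a, expressed by some dendritic cells and macrophages, 1726-fold. Both rest on few isotype counts, and without isotype replicate 1 they were 1764-fold and 1140-fold higher. Gfra2 (1882 counts against 1, ratio 2350, 95% counting interval 421 to 92850), Slc18b1 (714 against 1, ratio 891, interval 159 to 35256) and Cd207 (1763 against 3, ratio 734, interval 251 to 3561) followed, and Cd209f, with 0 counts in the libraries labelled isotype, was at least 531-fold higher over the group. The isotype counts of Gfra2, Slc18b1 and Cd207 came from isotype replicates 3, 2 and 1 alone, and were 0 without them. The fitted fold of Cd207 moved from 569 to 369 without isotype replicate 3, which held 0 of its counts. General macrophage genes did not move as a list: 6 rose, 5 fell and 4 were not called, with a median log2 fold change of 0.15 and a mean of -0.01 (camera adjusted p = 0.98). Csf1r, the receptor for macrophage colony-stimulating factor, rose 1.9-fold and Ms4a7 3.74-fold, while Fcgr1, the high-affinity immunoglobulin G receptor, fell 2.92-fold.

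**Figure D1:**
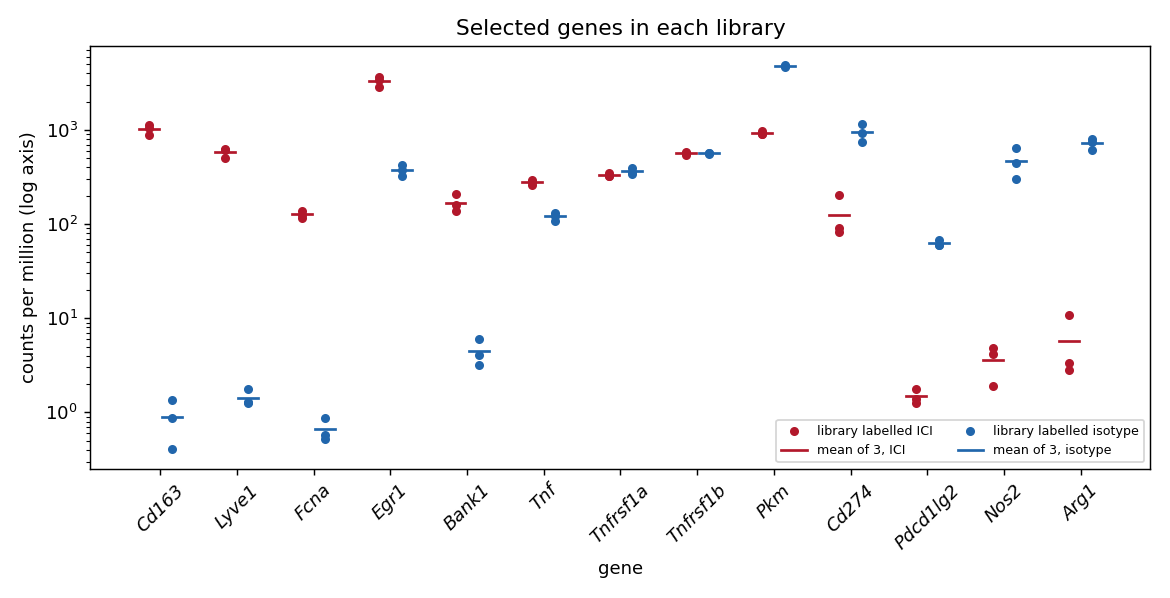
CPM (log axis) of 13 genes in each of the 6 libraries, red for libraries labelled ICI and blue for libraries labelled isotype, with a line at the mean of 3. Cd163 averaged 1029 CPM in the libraries labelled ICI and 0.884 CPM in those labelled isotype, while Nos2 averaged 3.63 and 463 CPM.

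Nos2 and Arg1 were among the 10 largest falls in the libraries labelled ICI. Nos2 (ENSMUSG00000020826), the inducible nitric oxide synthase, was at 3.63 ± 1.55 CPM against 463 ± 176 CPM, a log2 fold change of -7.21 (SE 0.52, edgeR adjusted p = 0.000116). Arg1 (ENSMUSG00000019987), the arginase that competes for the same substrate, was 148-fold lower at 5.68 ± 4.50 CPM against 719 ± 90.3 CPM (edgeR adjusted p = 0.000243), and 263-fold lower without ICI replicate 3. Among the 10 largest falls were also the chitinase-like gene Chil3 (40.3-fold), uridine phosphorylase Upp1 (84-fold), the interleukin-12 receptor chain Il12rb1 (50-fold), the PD-1 ligand gene Pdcd1lg2 (48.8-fold), Plekhg4 (47.4-fold), the guanylate-binding protein gene Gbp11 (45.3-fold), the activin subunit Inhba (37.3-fold; 58.8-fold without ICI replicate 1) and coagulation factor F7 (36.8-fold). Of the 32 interferon gamma response genes 28 fell and 0 rose, the same counts when adjusted over the list alone, with a median log2 fold change of -2.24 (camera adjusted p = 2.66e-07; adjusted p = 0.659 with an estimated correlation). Ido1 was 34-fold lower (53.1-fold without ICI replicate 2), Irf8 2.19-fold, and Ubd had 2 counts, both in ICI replicate 2, against 125 in the libraries labelled isotype (ratio 50.1 towards isotype, 95% counting interval 13.6 to 418). All 22 class I presentation genes fell, by a median of 1.13 on the log2 scale (camera adjusted p = 2.77e-05; adjusted p = 0.659 with an estimated correlation). Among them were the immunoproteasome subunit Psmb8 (4.15-fold lower), the peptide transporter chain Tap2 (3.04-fold), Tapbp (2.3-fold) and Pdia3 (1.87-fold). Class II presentation genes went both ways, with 3 higher, 5 lower and 8 not called (camera adjusted p = 0.26): Ifi30 and Ctss fell 5.71-fold and 3.11-fold, and H2-Ob rose 7.79-fold. Type I interferon genes were called 12 times lower and 5 times higher among 30 (camera adjusted p = 0.0912), with Ifi44 10.3-fold and Oasl1 4.39-fold lower and Oas2 3.9-fold higher. Without ICI replicate 2 this list was called lower (camera adjusted p = 0.000505; range over all alternatives 0.000505 to 0.764).

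Most glycolysis, nuclear respiratory chain and cell cycle genes of the lists were lower in the libraries labelled ICI as well. Of 20 glycolysis genes 18 fell and 2 rose, with a median log2 fold change of -2.09 (camera adjusted p = 2.42e-21; adjusted p = 0.0977 with an estimated correlation). Pyruvate kinase Pkm (ENSMUSG00000032294) was at 922 ± 46.1 CPM against 4780 ± 125 CPM, 5.97-fold lower (edgeR adjusted p = 4.74e-08), and Pgk1, Tpi1 and Pfkl were 7.24-fold, 6.8-fold and 4.36-fold lower. All 34 nuclear genes of the respiratory chain fell, by a median of 1.34 on the log2 scale (camera adjusted p = 9.73e-19; adjusted p = 0.571 with an estimated correlation). The cytochrome oxidase subunits Cox7b, Cox5a and Cox5b were 4.12-fold, 4.01-fold and 3.84-fold lower and the succinate dehydrogenase subunit Sdhb 3.06-fold lower. The share of mitochondrial transcripts, which this nuclear list leaves out, was instead higher in the libraries labelled ICI (0.783% against 0.446%, exact two-sided permutation p = 0.1). Cell cycle genes fell in 28 of 31 cases, with a median log2 fold change of -1.10 (camera adjusted p = 5.58e-07; adjusted p = 0.659 with an estimated correlation), including Aurka (2.97-fold), Mcm5 (2.95-fold), Ccnb1 (2.78-fold) and Bub1 (2.6-fold). Mki67, named after its value was seen, was not called (log2 fold change -0.28). Longer genes tended to be higher in the libraries labelled ICI (Spearman correlation of log2 fold change and transcript length 0.226 across genes).

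Tnf (ENSMUSG00000024401), the cytokine in the series title, was higher in the libraries labelled ICI. Its level was 279 ± 16.3 CPM against 121 ± 11.9 CPM, a 2-fold rise (log2 fold change 1.00, SE 0.10, edgeR adjusted p = 1.5e-05) that separated all 6 libraries. The immediate-early and heat shock genes described below rose in the same libraries, by a median of 2.73-fold. Whether the rise of Tnf shares a cause with theirs was not tested. Tnfrsf1b (ENSMUSG00000028599), which encodes TNFR2, was at 565 ± 20.5 CPM against 562 ± 7.92 CPM (log2 fold change -0.20, SE 0.08, edgeR adjusted p = 0.0522) and was not called. DESeq2 (adjusted p = 0.0434), limma-voom (0.0409), no filter (0.0352), the length correction (0.00432) and leaving out ICI replicate 1 (0.0442) put it past the threshold, within a range of 0.00432 to 1 over the alternatives. Tnfrsf1a (ENSMUSG00000030341), which encodes TNFR1, fell 1.26-fold (333 ± 16.9 CPM against 364 ± 28.1 CPM, edgeR adjusted p = 0.0108). That call was lost with upper-quartile factors (adjusted p = 0.178), library totals alone (0.213), the length and GC corrections (0.523 and 0.149) and against a 1.5-fold change, within a range of 0.00446 to 1 over the alternatives. Genes induced by TNF through NF-kB moved both ways, 14 higher, 11 lower and 8 not called among 33 (camera adjusted p = 0.732). Nfkbiz, an atypical inhibitor of NF-kB, rose 6.71-fold, while Tnfaip2 fell 4.37-fold and Bcl2a1d and Bcl2a1b fell 3.04-fold and 2.46-fold. Components of TNF signalling split into 11 higher and 12 lower of 30 (11 and 13 adjusted over the list alone; camera adjusted p = 0.396), with the kinase Map3k14 2.54-fold higher and the necroptosis kinase Ripk3 and the adaptors Tradd and Sharpin 5.48-fold, 2.19-fold and 2.1-fold lower. Inflammasome and lytic death genes fell in 11 and rose in 5 of 19 cases (camera adjusted p = 0.0481; adjusted p = 0.659 with an estimated correlation), including the necroptosis effector Mlkl (6.43-fold), Pycard (4.73-fold) and gasdermin D, Gsdmd (2.22-fold). That call was lost with upper-quartile factors (camera adjusted p = 0.0506), with the strict filter (0.108) and with the genes of other cells left out (0.0517), within a range of 0.0019 to 0.659.

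Immediate-early and heat shock genes, which tissue dissociation can induce, were all higher in the libraries labelled ICI. Each of the 23 members rose, by a median of 2.73-fold (camera adjusted p = 1.91e-14; adjusted p = 0.508 with an estimated correlation). Egr1 (ENSMUSG00000038418) was at 3288 ± 406 CPM against 374 ± 49.6 CPM (7.63-fold, edgeR adjusted p = 1.79e-07), Jun rose 5.83-fold, and the chaperone genes Hspb1 and Dnajb1 rose 37.6-fold and 3.46-fold. Chemokine genes rose in 15 and fell in 5 of 24 cases (camera adjusted p = 0.022; adjusted p = 0.508 with an estimated correlation). Ccl24, an eosinophil attractant, was 35.1-fold higher, Cxcl12 37.6-fold and the neutrophil attractant Cxcl2 2.54-fold, whereas Ccl5 was 3.1-fold lower. Chemokine receptors rose in 10 and fell in 4 of 16 cases (camera adjusted p = 0.483; 0.0236 in the male libraries alone; range 0.00905 to 0.729), with Ccr1 2.83-fold and Ccrl2 2.43-fold lower and Cxcr6 3.25-fold and Cxcr2 1.59-fold higher. Cxcr2 lost its call against a 1.5-fold change (adjusted p = 0.201; range 5.09e-05 to 0.201). Cytokine genes split into 6 higher and 8 lower of 23 (camera adjusted p = 0.732), with Il27 6.72-fold and Osm 2.01-fold lower and Il15 2.21-fold higher.

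Checkpoint and co-stimulation genes did not move as a list, with 11 higher, 9 lower and 6 not called among 26 (13 and 9 adjusted over the list alone; camera adjusted p = 0.677; the list median was 0.04 while camera's direction was down). Cd274 (ENSMUSG00000016496), which encodes the PD-1 ligand PD-L1, was 8.63-fold lower in the libraries labelled ICI, at 126 ± 67.4 CPM against 944 ± 197 CPM (edgeR adjusted p = 0.00224). Nectin2 was 6.34-fold lower, and the ligands Tnfsf9 and Icosl were 3.22-fold and 2.23-fold higher. The antibody targets themselves were scarce. Pdcd1 was at 1.63 ± 0.400 CPM against 0.563 ± 0.244 CPM (edgeR adjusted p = 0.00851) and lost its call in the male libraries alone (adjusted p = 0.0667; range over all alternatives 0.00417 to 0.0667). Ctla4 was at 5.37 ± 4.36 CPM against 1.20 ± 0.193 CPM (edgeR adjusted p = 0.0244), a 3.82-fold rise that was 2.11-fold without ICI replicate 3. It lost its call without isotype replicate 1, 2 or 3 (adjusted p = 0.0771, 0.0759 and 0.0697), with no filter (0.106) and against a 1.5-fold change (0.0598), within a range of 0.000114 to 0.106. Ifng was 2.36-fold higher, at 1.47 ± 0.172 CPM against 0.536 ± 0.193 CPM (edgeR adjusted p = 0.00632).

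**Figure D2:**
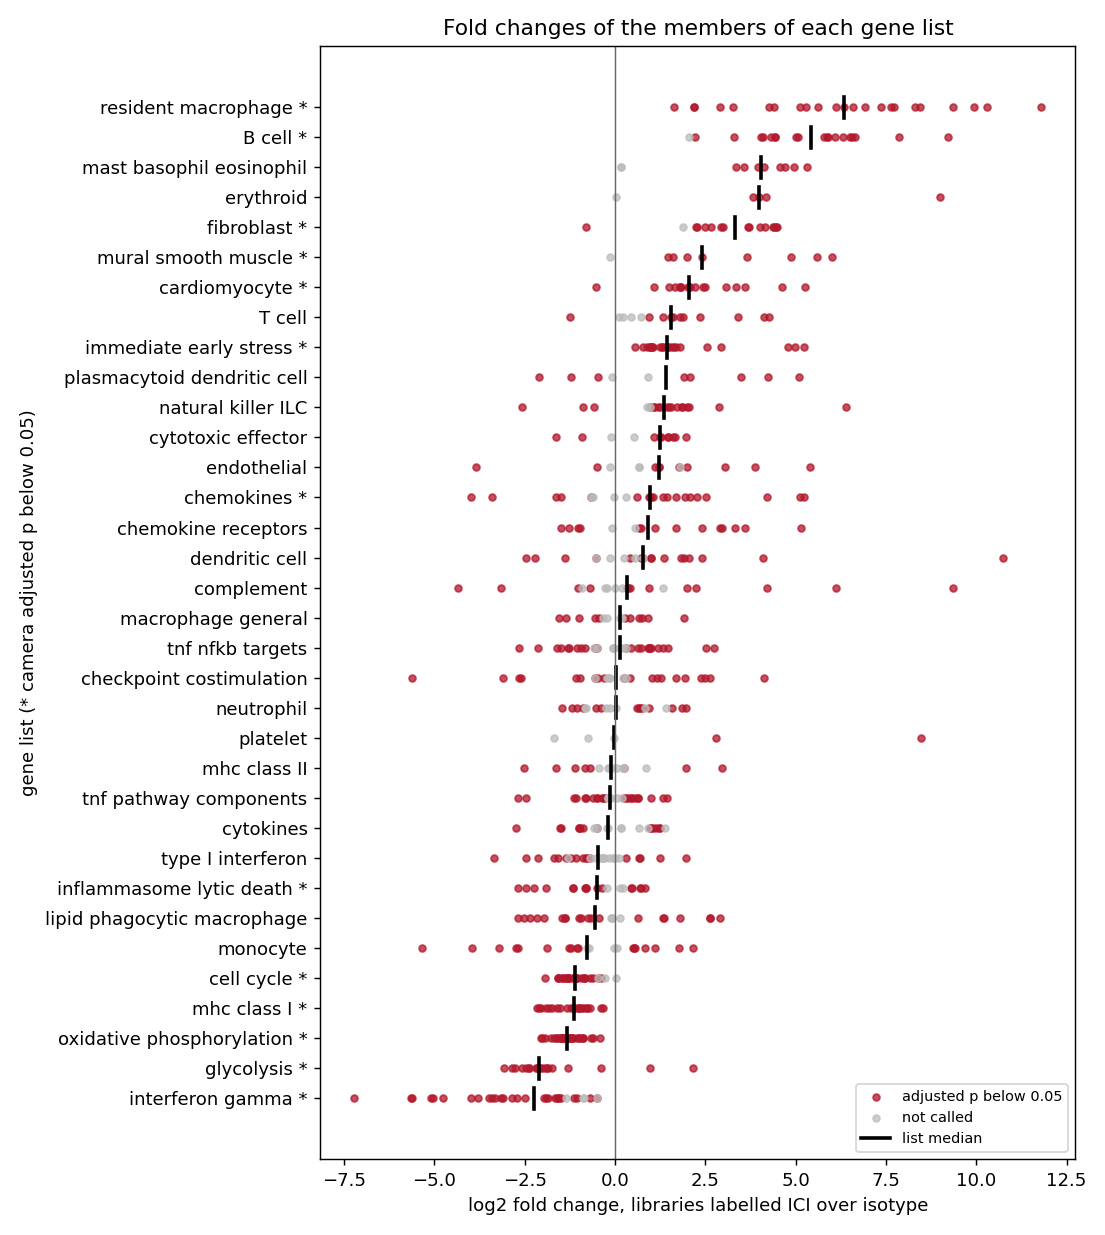
Log2 fold changes (libraries labelled ICI over isotype) of the tested members of the 34 gene lists, red where the gene was called at an adjusted p under 0.05 and grey where it was not, with a bar at each list's median and an asterisk at the 13 lists called by camera. The medians run from -2.24 for interferon gamma response genes to 6.33 for resident macrophage genes.

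Other myeloid lists were mixed. Monocyte genes fell in 10 and rose in 7 of 21 cases (camera adjusted p = 0.151), with F10 15.6-fold, Plac8 6.72-fold and Itgal 2.08-fold lower and Cd300e, a gene of patrolling monocytes, 4.47-fold higher. The list joins markers of classical and of patrolling monocytes, so opposite moves of these kinds can cancel in it. Of further members, named after their values were seen, Ly6c2 and Ccr2 fell (log2 fold change -3.22 and -1.02), and Ace and Spn rose (1.77 and 0.53). Without isotype replicate 3 the list was called lower (camera adjusted p = 0.00112; range over all alternatives 0.000464 to 0.687). Genes of lipid-handling and phagocytic macrophages fell in 13 and rose in 7 of 24 cases (camera adjusted p = 0.0623). They were called lower without ICI replicate 1 (0.0306) and without isotype replicate 1 or 3 (0.0419 and 0.0448), within a range of 0.00479 to 0.659. In that list Lgals3 fell 4.43-fold, lipoprotein lipase Lpl 3.89-fold and Msr1 2.76-fold, and the fatty acid transporter Cd36 rose 2.5-fold. Complement genes rose in 9 and fell in 4 of 19 cases (camera adjusted p = 0.112; 0.0249 without ICI replicate 2; range 0.00122 to 0.659), with the receptors C5ar2 and C5ar1 4.71-fold and 1.94-fold higher. Neutrophil genes rose in 8 and fell in 6 of 21 cases (camera adjusted p = 0.855), with S100a9 1.62-fold and Hdc 1.53-fold higher and Trem3 2.77-fold lower. S100a9 and Hdc lost their calls against a 1.5-fold change (adjusted p = 0.0704 and 0.363, the highest over their alternatives; lowest 9.35e-11 and 0.000104). Conventional dendritic cell genes rose in 12 and fell in 4 of 21 cases (camera adjusted p = 0.0623), with Zbtb46 3.77-fold and Kmo 3.58-fold higher and Naaa 4.63-fold lower. This list was called higher without ICI replicate 1 (camera adjusted p = 0.0338) and without isotype replicate 1 (0.0467) or 3 (0.00251), within a range of 0.00212 to 0.659. Plasmacytoid dendritic cell genes rose in 5 and fell in 3 of 10 cases (camera adjusted p = 0.24), with Tcf4 3.8-fold and Atp1b1 4.22-fold higher and Pacsin1 4.3-fold and Lair1 2.34-fold lower.

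B cell genes rose in the libraries labelled ICI in 19 of 20 cases, over all genes and adjusted over the list alone, with a median fold of 43.1 (camera adjusted p = 4.03e-07; adjusted p = 0.659 with an estimated correlation). Their summed level was highest in replicate 3 of each group. It was 1219, 1329 and 2571 CPM in replicates 1, 2 and 3 labelled ICI and 86.9, 74.9 and 132 CPM in those labelled isotype. The immunoglobulin heavy chain gene Ighm was at 746 ± 196 CPM against 65.7 ± 20.02 CPM (edgeR adjusted p = 4.56e-05). The signalling scaffold Bank1 rose 32.6-fold, Vpreb3 had 74 counts against 2 (ratio 46.2, 95% counting interval 12.3 to 389), and the plasma cell receptor Tnfrsf17, with 0 counts in the libraries labelled isotype, was at least 88.6-fold higher over the group. Natural killer and innate lymphoid genes rose in 15 and fell in 3 of 20 cases (camera adjusted p = 0.0526), with the interleukin-33 receptor Il1rl1 83.8-fold, Areg 7.38-fold and Ncr1 3.97-fold higher and Klrk1 5.95-fold lower. This list was called higher without ICI replicate 1 (camera adjusted p = 0.0106) and without isotype replicate 1 (0.0448), 2 (0.0428) or 3 (0.0482), with no robust estimation (0.0474) and after thinning to the lowest total (0.0447), within a range of 0.00917 to 0.665. Its summed level did not separate the groups (280.4 ± 48.99 CPM against 281 ± 7.67 CPM, exact two-sided permutation p = 1; ratio 0.866 on TMM effective sizes, p = 0.3), and Klrk1 made up 12.7% and 65.4% of it. Cytotoxic effector genes rose in 8 and fell in 2 of 12 cases (camera adjusted p = 0.194), with Fasl 3.9-fold, Prf1 2.76-fold and Nkg7 2.41-fold higher. Mast cell, basophil and eosinophil genes rose in 8 of 10 cases with 0 falls (camera adjusted p = 0.0623), among them Il5ra (39.7-fold), Gata2 (31.3-fold), Tpsab1 (26.1-fold) and Mcpt4 (23.6-fold). Il5ra was 23.3-fold higher without ICI replicate 3, and Tpsab1 69.8-fold and 17.3-fold without isotype replicate 3 and 1. The 13 isotype counts of Mcpt4 all came from isotype replicate 3, so that 0 were left without it, and the fold was 15.5 without isotype replicate 1. Leaving out ICI replicate 1 (0.0173) or isotype replicate 1 or 3 (0.0473 and 0.0129) made this list a call, within a range of 0.00264 to 0.665. Its sum was 71.9 ± 39.0 CPM against 22.2 ± 8.32 CPM (exact two-sided permutation p = 0.1), with Kit, named after its values were seen, at 27.9% and 69.7% of it.

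Of the 2 markers of the gate, Ptprc, which encodes CD45, was at 1300 ± 107 CPM against 1012 ± 58.8 CPM (log2 fold change 0.16, SE 0.10, edgeR adjusted p = 0.164). It was called higher with upper-quartile factors (0.0102), library totals alone (0.00551) and the strict filter (0.0449), and its sign turned with the length and GC corrections, within a range of 0.00551 to 1. Thy1, which encodes CD90, had 0 to 2 counts in each library, and Cd3e, named outside the rule after its values were seen, had 4 to 17. T cell genes rose in 10 and fell in 1 of 15 cases (camera adjusted p = 0.0623; 0.0432 without ICI replicate 1 and 0.0447 after thinning to the lowest total; range 0.0117 to 0.665), among them Cd4 (19.1-fold; 30.8-fold without isotype replicate 3), Cd28 (17.6-fold) and Lck (3.46-fold). Their summed level was 56.1 ± 17.5 CPM against 12.4 ± 1.55 CPM (exact two-sided permutation p = 0.1), and Cd4, Lck and Cd28 made up 25.5%, 21.3% and 15.6% of it in the libraries labelled ICI. Of the genes of the T cell receptor complex, Cd3e and Trbc2 were not called (log2 fold change 0.21 and 0.12), Cd3g, Cd247 and Trbc1 rose (1.60, 1.34 and 0.94) and Trac was the 1 that fell (-1.23). Cd3d, with 1 to 8 counts in each library, was not among the tested genes. Cd3d, Cd3g, Cd247, Trac, Trbc1 and Trbc2 were also named after their values were seen.

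Most markers of cardiomyocytes, fibroblasts and mural cells were higher in the libraries labelled ICI. Cardiomyocyte genes rose in 17 and fell in 1 of 18 cases (camera adjusted p = 0.00118; adjusted p = 0.659 with an estimated correlation), with myoglobin, Mb, at 10.5 ± 2.24 CPM against 0.353 ± 0.167 CPM and Tnni3 3.47-fold higher. Fibroblast genes rose in 14 and fell in 1 of 16 cases (15 and 1 adjusted over the list alone; camera adjusted p = 0.00402; adjusted p = 0.665 with an estimated correlation), with Dpt 22.5-fold, Tcf21 20.9-fold and Pcolce 13.2-fold higher. Mural and smooth muscle genes rose in 8 of 9 cases (camera adjusted p = 0.0152; adjusted p = 0.659 with an estimated correlation), with Rgs5 65-fold and Myh11 29.6-fold higher (141-fold without isotype replicate 3 and 46.7-fold without isotype replicate 1). Endothelial genes rose in 8 and fell in 2 of 14 cases (camera adjusted p = 0.194), with Aqp1 42.1-fold higher and Flt1, which encodes a receptor for vascular endothelial growth factor, 14.3-fold lower. Erythroid genes rose in 4 of 5 cases (camera adjusted p = 0.0623), with Hbb-bs at 10.9 ± 4.67 CPM against 0.548 ± 0.407 CPM (18.1-fold higher; 28.4-fold without isotype replicate 2) and Hbb-bt, with 0 counts in the libraries labelled isotype, at least 75.2-fold higher over the group. The erythroid list was called higher without ICI replicate 3 (0.0324) and without isotype replicate 2 or 3 (0.039 and 0.0346) and with the length trend removed (0.0419), within a range of 0.00299 to 0.659. Platelet genes rose in 2 of 5 cases (camera adjusted p = 0.376; the list median was -0.03, or 1.52 without ICI replicate 1, while the mean was 1.76), with Ppbp at 454 counts against 1, in isotype replicate 1 (ratio 567, 95% counting interval 101 to 22435). Summed over each list on library totals, the cardiomyocyte markers did not separate the groups (293 ± 12.3 CPM against 284 ± 15.1 CPM, exact two-sided permutation p = 0.5). On TMM effective sizes, the scaling of the gene tests, their sum was lower in every library labelled ICI (274 ± 6.63 against 306 ± 21.2, exact two-sided permutation p = 0.1). The fibroblast sum did not separate the groups on either scale (706 ± 265 CPM against 874 ± 167 CPM on totals, exact two-sided permutation p = 0.4, and 0.3 on TMM effective sizes). The endothelial sum was lower in every library labelled ICI (146 ± 13.5 CPM against 251 ± 24.6 CPM, exact two-sided permutation p = 0.1), with Flt1 at 8.36% and 60.7% of it. The mural (26.6 ± 5.97 CPM against 5.67 ± 1.38 CPM), erythroid (36.2 ± 9.21 CPM against 7.72 ± 0.493 CPM) and platelet sums (15.6 ± 5.31 CPM against 3.01 ± 0.348 CPM) were higher in every library labelled ICI (exact two-sided permutation p = 0.1 each). Adjusted over the 12 sums and single genes compared in this way, a p of 0.1 became 0.133. Atp2a2 made up 74.6% and 95.3% of the cardiomyocyte sums, and Gsn 79.2% and 98.2% of the fibroblast sums. Each was the 1 member of its list that fell (Atp2a2 219 ± 5.55 CPM against 271 ± 20.7 CPM, Gsn 559 ± 171 CPM against 858 ± 164 CPM). The cardiomyocyte and fibroblast sums therefore mostly follow these genes. They do not show that the other markers, most of which rose, were alike between the groups. Atp2a2 and Gsn were named outside the rule, after their values were seen.

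**Figure D3:**
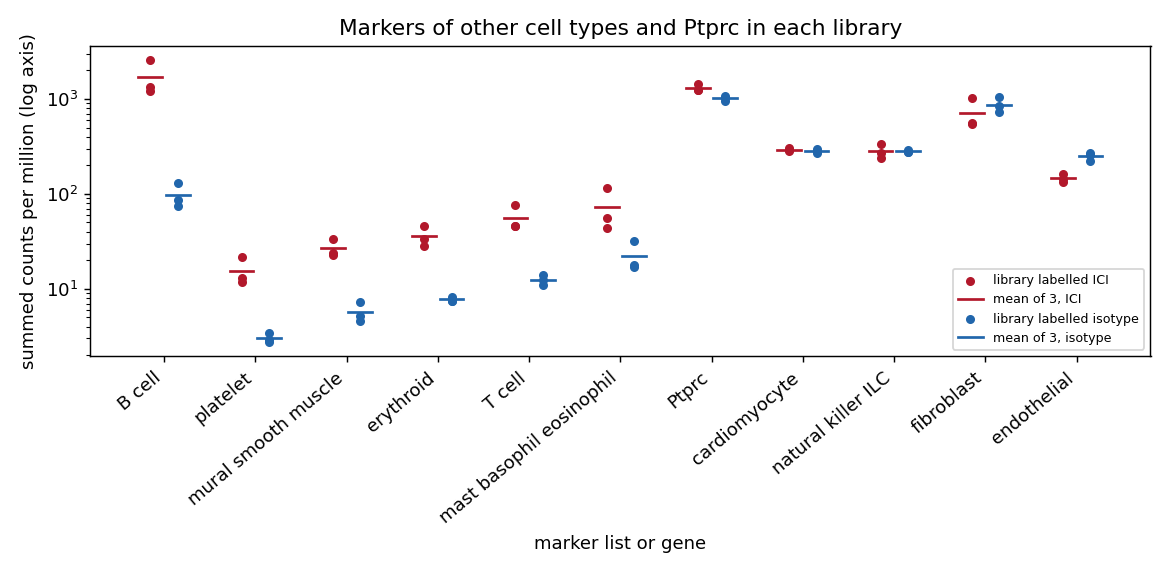
Summed CPM (log axis) of the markers of 10 other cell types, and of Ptprc, in each of the 6 libraries, red for libraries labelled ICI and blue for libraries labelled isotype, with a line at the mean of 3. B cell markers averaged 1706 CPM in the libraries labelled ICI and 97.8 CPM in those labelled isotype, while endothelial markers averaged 146 and 251 CPM. Flt1 alone made up 8.36% and 60.7% of the endothelial sums, and of 14 endothelial genes tested 8 were called higher and 2 lower.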

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

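The length, GC, sex, male-only and thinning alternatives were chosen after the data were seen. Called genes numbered 9124 to 9938 without 1 replicate (4624 to 5068 higher, 4500 to 4870 lower) and 5520 (3110 and 2410) against a 1.5-fold change, a stricter hypothesis by construction; with every other alternative they stayed within 1.5 times the reported count. With DESeq2, 9256 of the 10040 calls were kept in the same direction. A called gene turned direction while still called in 4 cases with the length trend removed and in 1 with the GC trend removed, and in 0 cases with the other alternatives. Of 186 genes named by rule or chosen by abundance, 182 were called and 174 kept their call and direction in all alternatives that tested them.

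The number of lists called was 14 to 19 without 1 replicate, 22 with no filter, 20 with a sex term, 28 with fry and 0 with an estimated correlation. It was 8 with the genes of other cells left out, which removes 4 of the 13 called lists. The causes of the other moves were not tested. The replicate block gave 21 lists and 9991 genes. Same-numbered libraries deviated together by correlations of 0.03, 0.06 and 0.13, not all over 0.1, and ICI replicate 2 correlated best with isotype replicate 1 (0.09), so the numbers were not taken as pairs. Differently numbered libraries ran from -0.14 to 0.09, and replicate 3 carried more Xist than Y-linked counts in both groups. With 3 libraries per group these values cannot exclude pairing. Lists that the block called in addition were type I interferon and monocyte genes, lower, and conventional and plasmacytoid dendritic cell, natural killer, T cell, mast cell and erythroid genes, higher. The sex term called these too, except the plasmacytoid dendritic cell list. With no filter they were called as well, again except the plasmacytoid list, together with the complement and lipid-handling macrophage lists. The male libraries alone added the monocyte, conventional dendritic cell, mast cell, erythroid and chemokine receptor lists.

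Among the lists and the named genes, directions that turned belonged to values not called in either setting. General macrophage genes turned in camera's direction while their median was 0.33 with upper-quartile factors, 0.35 with library totals alone, 0.23 with the strict filter, 0.16 with other cells' genes left out, 0.025 to 0.24 without 1 replicate (0.24 without ICI replicate 2 and 0.17 without isotype replicate 3 turned), -0.13 and 0.12 with the length and GC trends removed, 0.075 in male libraries and 0.15 with fry. The camera direction of NF-kB targets turned without isotype replicate 3 (0.093; range without 1 replicate 0.090 to 0.17) and in male libraries (0.075), and that of neutrophil genes with no filter (-0.17) and without ICI replicate 1 (-0.13) or isotype replicate 3 (-0.0091; range -0.13 to 0.029). The median alone changed sign for NF-kB targets with the length trend removed (-0.063) and for neutrophil genes without ICI replicate 3 (-0.029) or isotype replicate 1 (-0.024) and with the GC trend removed (-0.035). It also did so for TNF signalling components with upper-quartile factors (0.039) and library totals alone (0.061), for checkpoint genes with no filter (-0.065), the strict filter (-0.083) and other cells' genes left out (-0.12), and in several settings each for class II (up to 0.15), cytokine (up to 0.093) and platelet genes (up to 1.63). Ptprc turned with the length (-0.13) and GC (-0.10) trends removed, and Tnfrsf1b with library totals alone (0.0073). The ratio of the cardiomyocyte sums turned from 1.03 on library totals to 0.896 on TMM effective sizes, where every library labelled ICI was lower. The causes were not tested. Genes with few counts are limited by depth: 3 counts over a group are 0.0353 CPM in the libraries labelled isotype and 0.0441 CPM in those labelled ICI.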

Other observations

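Among abundant transcripts outside the named set, chosen after their values were seen by the size of the CPM difference, the libraries labelled ICI held more of the lipid carrier gene Apoe (6988 ± 1776 CPM against 982 ± 433 CPM, SD of 3 libraries), the transglutaminase gene F13a1 (4397 ± 477 CPM against 197 ± 49.3 CPM), the iron carrier gene Trf (19.8-fold), the phospholipid transfer gene Pltp (20.2-fold) and the mannose receptor gene Mrc1 (21-fold). The libraries labelled isotype held more of the complement factor gene Cfb (20.4-fold), Ly6a (35.3-fold), the transglutaminase gene Tgm2 (14.3-fold), the lysosomal genes Psap (2.69-fold) and Ctsd (2.6-fold), and the glycolytic genes Ldha (4.54-fold) and Aldoa (5.24-fold). Gbp2 was 7.22-fold lower in the libraries labelled ICI (edgeR adjusted p = 0.0234; 13.2-fold without ICI replicate 2) and lost its call without ICI replicate 1 (0.077), isotype replicate 1 (0.0551) or isotype replicate 2 (0.067), within a range of 0.000161 to 0.077 over the alternatives. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) called as many genes: it called 10040, and the highest of the other splits called 0. With 10 splits the share cannot fall under 0.1, too few to judge chance.

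The tests of the composition factors, of the labels and of the B cell genes below were chosen after the result was seen. Interferon gamma response genes were lower in the libraries labelled ICI, although the protocol label says that the checkpoint antibodies induced myocarditis. The titles of the libraries labelled isotype name myocarditis as well, so the labels do not mark those hearts as free of it. The list median was -2.24 in the main fit, -2.22 after thinning to the lowest total and -2.04 with library totals alone. Neither setting could have removed a fall of this size, so they do not weigh its causes. Thinning keeps the expected share of each gene, and dropping the factors moved the median of all genes only from 0.03 to 0.23. A single wrong label would put 1 library with the other group, and 6 of 6 libraries correlated best with a library of their own group, which argues against it. An exchange of the labels of both whole groups would turn each sign and cannot be told apart from an effect of the antibodies, because nothing in these counts marks which mice received them; that 0 libraries labelled ICI reached the list mean of a library labelled isotype restates the fall and says nothing for or against an exchange. A lower interferon gamma response of non-T immune cells after checkpoint inhibition at the time sampled stays open as untested. Bulk libraries cannot tell a change within cells from a difference in which cells were sampled. All 23 resident macrophage genes were higher in the libraries labelled ICI, by a median of 80.6-fold.

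Glycolysis and nuclear respiratory chain genes were lower in the libraries labelled ICI, and longer genes were higher there. A length or GC bias could therefore lower these lists. With the gene length trend removed the medians were -1.91 for glycolysis and -1.03 for the respiratory chain, and with the GC trend removed -2.02 and -1.30, with upper quartiles below 0 in all 4 cases (-1.64, -0.81, -1.69 and -1.02). Neither trend accounts for the whole fall. A difference in the activation of the cells between the labelled groups is an open hypothesis that was not tested. Bulk libraries cannot tell it from a difference in which cells were sampled.

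B cell genes were higher in the libraries labelled ICI. A lower share of macrophages could raise the markers of every other cell type alike. The median log2 fold change of the 20 B cell members (5.43) exceeded that of 91 pooled members of the T cell, natural killer, neutrophil, dendritic cell and endothelial lists (0.97) by 4.46. In these lists 10, 15, 8, 12 and 8 genes were called higher and 1, 3, 6, 4 and 2 lower. Members that fell, such as Flt1 (-3.84) and Klrk1 (-2.57), lower the pooled median whatever the share of macrophages. Those 5 lists leave out the mast cell (median 4.04), erythroid (3.98), fibroblast (3.34) and mural lists (2.40), which rose further. Against 164 pooled members of 12 lists with these included (median 1.64) the excess was 3.79. Permutation tests over genes gave two-sided p = 1e-05 for both, the smallest that 100000 permutations can give. Genes are not independent, and the estimated correlation of the B cell members was 0.801, so these p-values overstate the evidence. General macrophage genes did not fall as a list (6 higher, 5 lower and 4 not called, median 0.15). The comparison shows that B cell genes rose further than the pooled genes, but it cannot decide whether a lower share of macrophages contributed. B cell genes did not exceed every list in every setting. Without isotype replicate 3 the mast cell median was 6.13, against 4.98 to 5.68 for B cell genes without 1 library. In fits without 1 library the mural median ran from 1.82 to 3.61 and the erythroid median from 3.31 to 4.54. A larger share of B cells, which the sort on CD45 and CD90.2 does not remove, or blood left in the hearts of the libraries labelled ICI, stays open and was not tested.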
